A study of Drosophila melanogaster with 3 samples.

How the data were processed

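Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on whole fruit fly embryos aged 0 to 24 h, of mixed sex, from a line that carries CG7839 fused at its C-terminus to GFP. Per the labels, the protein was precipitated with an antibody against GFP and the chromatin was broken by sonication. The labels number 3 biological replicates, all in 1 group, and name no other group, so no comparison between groups was possible. CG7839 is annotated as Noc1, a member of the nucleolar complex proteins known from yeast for their part in making the large ribosomal subunit.

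Each replicate has a peak list that the authors made from its own alignments and 1 control common to all 3 replicates, per the text files deposited beside the lists. A pooled list was derived from the 3 alignments with the same control. A list named for a threshold on the irreproducible discovery rate, called the IDR list here, was derived from the replicate and pooled lists. All lists are on the dm6 assembly. The aligner, peak caller, thresholds and read filters are not given in the sources used here, and the control was not analysed here. The replicate and pooled lists each hold exactly 30000 summits, and the IDR list holds 8188. The deposited signal value of each peak has no stated scale, so it is the authors' value and was used only to rank peaks within a list. The deposited −log10 q value is 1 constant in the IDR list and was not used to rank. The 8188 IDR peaks are the 8188 pooled peaks of largest signal value. Membership in the IDR list is thus the same as a cutoff on pooled signal. Between 2 and 7 summit offsets per list lay past the end of their interval and were placed on its last base. Read depth per sample is unknown from these files. Intervals on shares cover counting error over peaks or genes only, and neighbouring peaks and genes are not fully independent.

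Genes came from Ensembl release 115 and sequence from the RefSeq assembly, both on dm6 coordinates and restricted to arms 2L, 2R, 3L, 3R, 4, X and Y. A promoter was the 500 bp on either side of any annotated transcript start. Each summit was given 1 class in the order promoter, 5′ UTR, coding exon, 3′ UTR, non-coding exon, intron and intergenic. Chance shares came from 1000 circular shifts of the summits along each arm, with two-sided empirical p-values of which 0.002 is the smallest they can give. Replicates were compared on the 8188 peaks of largest signal value in each list, with summits within 100 bp counted as shared and a one-sided permutation p of which 0.000999 is the smallest. Because the replicate lists share a control, part of their overlap may come from it, and this was not simulated since no control reads were used here. No summit of 1 replicate matched another replicate's in both position and signal value.

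Protein-coding genes with a promoter summit, called bound here, were compared between each of 23 gene lists of at least 5 members and all others of the 13968 protein-coding genes, by Fisher's exact test, two-sided. Strength among bound genes was compared by a permutation test of the mean signal percentile with 100000 resamples. Non-coding classes were tested against circular shifts over the 500 bp around the gene start. A set of 20 sequence motifs was searched on both strands in the 201 bp around each summit and around points 1000 bp to each side, with an exact sign test, and in the 201 bp around gene starts of bound and other genes, with Fisher's exact test. All families were adjusted by the Benjamini-Hochberg method at 0.05, and every adjusted p for a gene list is adjusted over the lists alone. Arms were compared with their share of length and of transcript starts by exact binomial tests. Shares have 95% Wilson intervals, and where a count is 0 the limit given is 3 counts of the total. Values ± SD are over the 3 replicates' own 8188 strongest peaks unless said otherwise. The p-values of tests on the IDR list measure chance placement of 1 pooled peak set and not the spread between embryo collections.

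Gene lists, motifs, tests, the named-gene rule and most alternatives were fixed before the data were examined. The rule named the genes nearest the 25 strongest IDR peaks, up to 4 members with the strongest promoter peaks in each list that passed and in each non-coding class, the tagged gene, white and the other nucleolar complex genes, and the 3 strongest peaks over 2000 bp from any transcript start. Alternatives were other promoter windows (250 and 1000 bp), other summit distances (50 and 250 bp), 50% reciprocal overlap, the upper 4094 IDR peaks, leaving out each replicate, other backgrounds, other rules for assigning summits and other motif windows. Leaving out a replicate kept the IDR peaks with a matching strong summit in both others (5984, 6045 and 6130 peaks), which also makes the list stricter. Comparisons matched on GC content were chosen after the data were seen. They used random positions on the same arm with the same GC count over 201, 101 or 401 bp (200 draws for annotation and non-coding classes, 10 for positions around transcript starts, 1 for motifs and words), or 10 strata of GC with the Cochran-Mantel-Haenszel test.

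The tests were tried on simulated data over the 13968 genes. Peak sets with 4 changed lists were drawn 20 times, and each changed list was recovered with its direction 20 times of 20. Lists left unchanged were called 7 times of 360. Uniform peak sets were called by the shift test 0 times of 40, a motif planted in windows was recovered 10 times of 10, and unplanted motifs were called 0 times of 170. CGATA and GATA were not among these unplanted motifs. The simulated windows lay at uniform positions, whereas the real summits had 33.5% GC against 41.8% in their flanks. The 0 of 170 therefore does not cover calls that such a difference in composition can cause. The permutation test of signal ranks and the stratified test were not simulated. Scripts ran in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.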

Results

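Peaks of GFP-tagged CG7839 (Noc1) were measured by ChIP-seq in whole embryos aged 0 to 24 h, in 1 group of 3 biological replicates. The data are lists of peak summits on dm6: 30000 in each replicate, 30000 from the pooled reads and 8188 in the IDR list. The IDR summits are the pooled ones of largest signal value. Read depth is unknown from these files, and no untagged or unrelated group was analysed here as background.

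The first question the design raises is whether the replicates found the same places. The strongest peak of the IDR list lay 96 bp upstream of CG14100 on arm 3L (start 19590357, end 19590881, summit 19590620) and ranked 1, 2 and 2 in replicates 1, 2 and 3. The next, 31 bp upstream of Ugalt, a UDP-galactose transporter gene on X (summit 2703883), ranked 2, 1 and 1. The peak 135 bp upstream of mRpL41, which encodes a mitochondrial ribosomal protein (2R, summit 15217752), ranked 3, 5 and 5. Of the 8188 strongest peaks of replicate 1, 75.9% (Wilson interval 74.95 to 76.8) had a summit within 100 bp among those of replicate 2, and 76.2% among those of replicate 3. Replicates 2 and 3 shared 77.0%. Circular shifts gave 1.24% for each pair, and each permutation p of 0.000999 is the smallest the 1000 shifts can give. Finding summits of the IDR list back is no separate measure. That list holds the pooled peaks of largest signal value, drawn from these same replicates' alignments. Of its 8188 summits, 67.3% were among the strongest peaks of all 3 replicates and 87.1% among those of 2 or more, against 89.6% and 99.1% in the replicates' full lists. Matched summits lay a median of 20 to 22 bp apart. Across matched IDR peaks, which are not independent replicates, the Spearman correlation of signal ranks was 0.872, 0.885 and 0.883 for the 3 pairs.

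The second question is where in the genome the peaks lie. Promoters held 3036 of the 8188 IDR summits (37.1%, Wilson interval 36.0 to 38.1), 2.74 times the 13.6% of shifted positions (permutation adjusted p = 0.0028, at the smallest p the shifts can give). Coding exons held 13 summits (0.159%) against 13.7% by chance, a fold of 0.0116 with the same adjusted p. Summits were also fewer in 3′ UTRs (0.205-fold), 5′ UTRs (0.547-fold) and intergenic DNA (0.697-fold), each with an adjusted p of 0.0028. By the class order, each of these classes holds only DNA outside the promoter windows. In the replicates' own lists the promoter share was 39.6% ± 2.92 (SD, n = 3) and the coding-exon share 0.171% ± 0.0122 (SD, n = 3). Introns held 3397 summits, 1.05 times chance (permutation adjusted p = 0.0256), but 0.945 times the share of GC-matched positions (permutation adjusted p = 0.0139), so their direction turned with the background, and in the upper 4094 peaks they did not pass (1.02-fold). Non-coding exons did not pass (1.23-fold, permutation adjusted p = 0.12) but did with a 250-bp promoter (1.26-fold, permutation adjusted p = 0.024). Against GC-matched positions the coding-exon fold was 0.0458, the 3′ UTR fold 0.111 and the promoter fold 2.62. With a 1000-bp promoter the coding-exon fold was 0.007 and the 5′ UTR fold 0.350, and 5′ UTRs did not pass when matched on GC in the smaller window (0.722-fold).

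**Figure D1:**
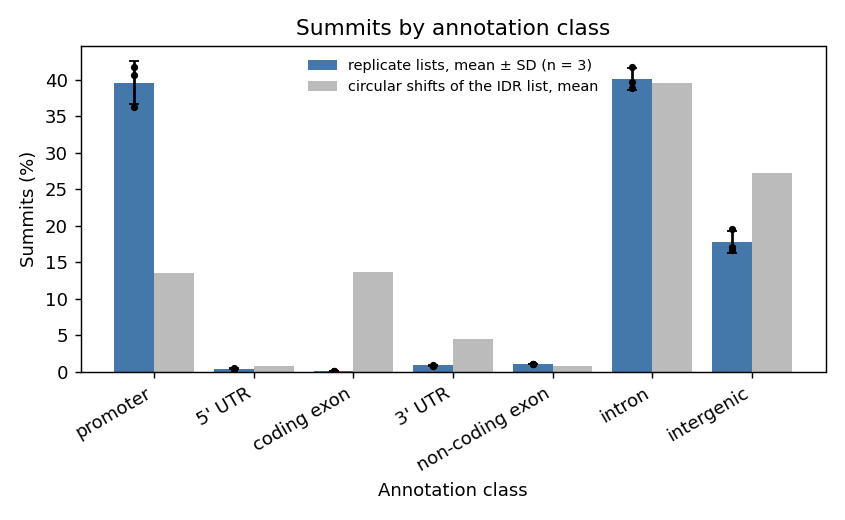
Share of summits (%) in each annotation class: mean and SD of the 3 replicates' own 8188 strongest peaks (blue, points for replicates) and mean of shifted IDR summits (grey). Promoters stand at 39.6% against 13.6%, and coding exons at 0.171% against 13.7%.

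Promoter summits lay upstream of the transcript start more often than GC-matched positions did. Of 2806 summits within 500 bp of a protein-coding start, 2258 (80.5%, Wilson interval 79.0 to 81.9) were upstream, with a median position of -128 bp, and 65.1% of GC-matched positions in the same range were also upstream. The fullest 50-bp bin began at -150 bp and held 463 summits, against a mean of 78.1 for GC-matched positions. Among the 25 strongest peaks, those near CG13390 (-83 bp), CHMP2B, an ESCRT-III gene (-111 bp), CenG1A (-110 bp) and Cp190's fellow insulator gene Chro (88 bp downstream, in the 5′ UTR but classed as promoter) lay close to a start. Others lay in introns, at Trl, which encodes the GAGA factor (1533 bp downstream of a start), Lk6 (969 bp upstream of a start), HmgZ (566 bp upstream of a start), CG32772 and CG11050. The strongest peak over 2000 bp from any start was intergenic on 2L (summit 1638794), 8369 bp from lncRNA:CR45695. The next were in an intron of Tlk on X (summit 3742225), 2328 bp from a start, and intergenic on 2R (summit 13035340), 11916 bp from CG13323.

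**Figure D2:**
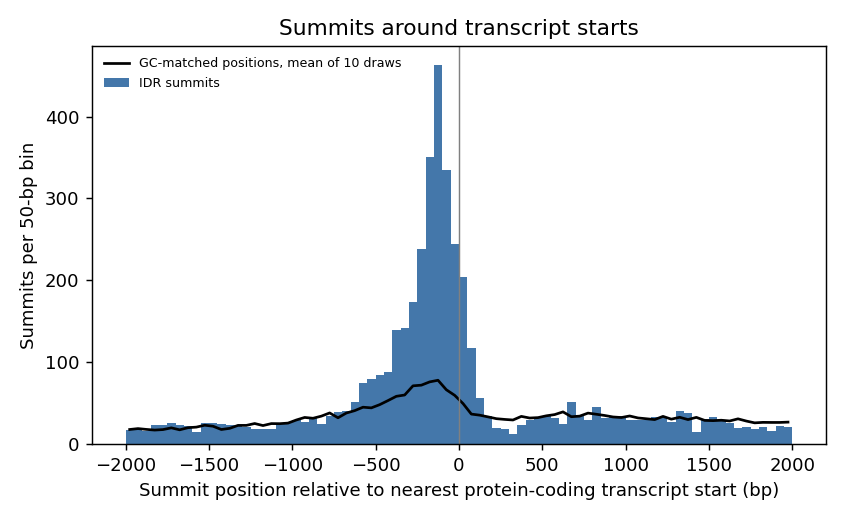
Number of IDR summits per 50-bp bin by position relative to the nearest protein-coding transcript start (bp, negative is upstream), with the mean of 10 draws of GC-matched positions as a black line. The fullest bin begins at -150 bp and holds 463 summits against 78.1.

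The third question is which genes carry promoter peaks. In all, 3187 of 13968 protein-coding genes were bound (22.8%, Wilson interval 22.1 to 23.5). Cytoplasmic ribosomal protein genes were bound most often of the 23 lists: 72 of 92 (78.3%), an odds ratio of 12.2 (95% interval 7.48 to 21.6, Fisher adjusted p = 4.3e-28), and 79.0% ± 2.74 (SD, 3 replicates) in the replicates' own lists. Among genes with a pooled-list promoter peak the odds ratio was 7.38. The IDR list is the top of the pooled list, so here and below this filter depends on the outcome. It asks only whether a gene's pooled peak is among the strongest. The strongest were RpS27 (21 bp upstream, mean rank 363 ± 108, SD over 3 replicates), RpL34b (116 bp upstream, 503 ± 97.7), RpL23A (78 bp upstream, 802 ± 267) and RpL14 (35 bp upstream, 751 ± 151). The peak of RpL14 is shared with Nelf-E, which encodes a subunit of the negative elongation factor and starts on the opposite strand.

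Mitochondrial ribosomal protein genes were bound in 30 of 73 cases (41.1%, odds ratio 2.38, Fisher adjusted p = 0.0023), led by mRpL41 and mRpS10. The mRpS10 peak (3R, summit 15229536) is shared with Art3, a protein arginine methyltransferase gene, and that of mRpS23 with CenG1A. With each summit given to its nearest start only, the odds ratio was 1.03 (Fisher adjusted p = 1). It was 1.80 without replicate 1 (Fisher adjusted p = 0.0641) and 1.90 without replicate 3 (Fisher adjusted p = 0.0611).

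Insulator and promoter factor genes were bound in 12 of 21 cases (57.1%, odds ratio 4.46, Fisher adjusted p = 0.0023). These included Chro, Cp190 (135 bp upstream, mean rank 86.3 ± 16.9, SD over 3 replicates) and M1BP (260 bp upstream). Abundant housekeeping genes outside translation were bound in 17 of 29 cases (58.6%, odds ratio 4.76, Fisher adjusted p = 0.00016), among them the glycolytic genes Gapdh2, Eno and Pgk and the chaperone gene Hsp83. Among genes with any pooled-list promoter peak, neither list passed (odds ratio 1.248, Fisher adjusted p = 0.855, and 1.34, Fisher adjusted p = 0.605). As that filter depends on the outcome, it does not decide whether these promoters carry peaks more often than others. The insulator list also did not pass with nearest starts only (2.92, Fisher adjusted p = 0.0734).

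Among the 23 lists, 3 passed as bound less often than other genes: cuticle protein, chemoreceptor and histone genes. Cuticle protein genes were bound in 2 of 120 cases (1.67%, odds ratio 0.0706, Fisher adjusted p = 2.1e-10), Cpr65Ea and Cpr67Fa1. Chemoreceptor and odorant-binding genes were bound in 4 of 230 cases (1.74%, odds ratio 0.0659, Fisher adjusted p = 1.8e-19), namely Obp99b, Obp83g, Obp83cd and Gr77a. Among genes with a pooled-list promoter peak the chemoreceptor odds ratio was 0.253, and with a 1000-bp promoter that of cuticle genes was 0.178. Replication-dependent histone genes had 0 of 111 bound (Fisher adjusted p = 3.7e-12), which allows a share of up to 2.7% by a limit of 3 counts (Wilson upper limit 3.35%), and none had a promoter summit in the pooled list either. Their copies are near-identical repeats, in which reads may not be placed uniquely.

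The other 16 lists did not pass. Ribosome assembly factors were bound in 14 of 38 cases (odds ratio 2.01, Fisher adjusted p = 0.107) and aminoacyl-tRNA synthetases in 14 of 35 (2.29, Fisher adjusted p = 0.062). Patterning transcription factors were bound in 4 of 44 cases (0.375, Fisher adjusted p = 0.0683), neuronal genes in 3 of 33 (0.387, Fisher adjusted p = 0.12) and digestive proteases in 1 of 27 (0.191, Fisher adjusted p = 0.0536). Translation factors (16 of 54), chaperones (12 of 36), spliceosome genes (8 of 29) and RNA polymerase I and III subunits (5 of 17) had odds ratios of 1.34 to 1.73. Proteasome genes (11 of 48, odds ratio 1.04), oxidative phosphorylation genes (19 of 86, 0.977), muscle genes (6 of 25) and germline genes (6 of 24) were near the rest. Cell cycle genes were bound in 10 of 40 cases in the IDR list but in 37.5%, 27.5% and 52.5% in the replicates' own lists, where spliceosome genes reached 48.3% and ribosome assembly factors 60.5% in replicate 3. Egg shell and yolk genes (2 of 17) and hemocyte and fat body genes (1 of 17) were the remaining lists. Of the nucleolar complex genes, too few to test, Noc2 had an IDR peak 183 bp upstream that was matched in replicate 1 alone, and Noc1 itself, Noc3 and CG2875 had none, nor did white. CG2875 had a promoter summit in the pooled list, and among the strongest peaks of replicates 1, 2 and 3 the share of these 4 genes bound was 25%, 25% and 50%.

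**Figure D3:**
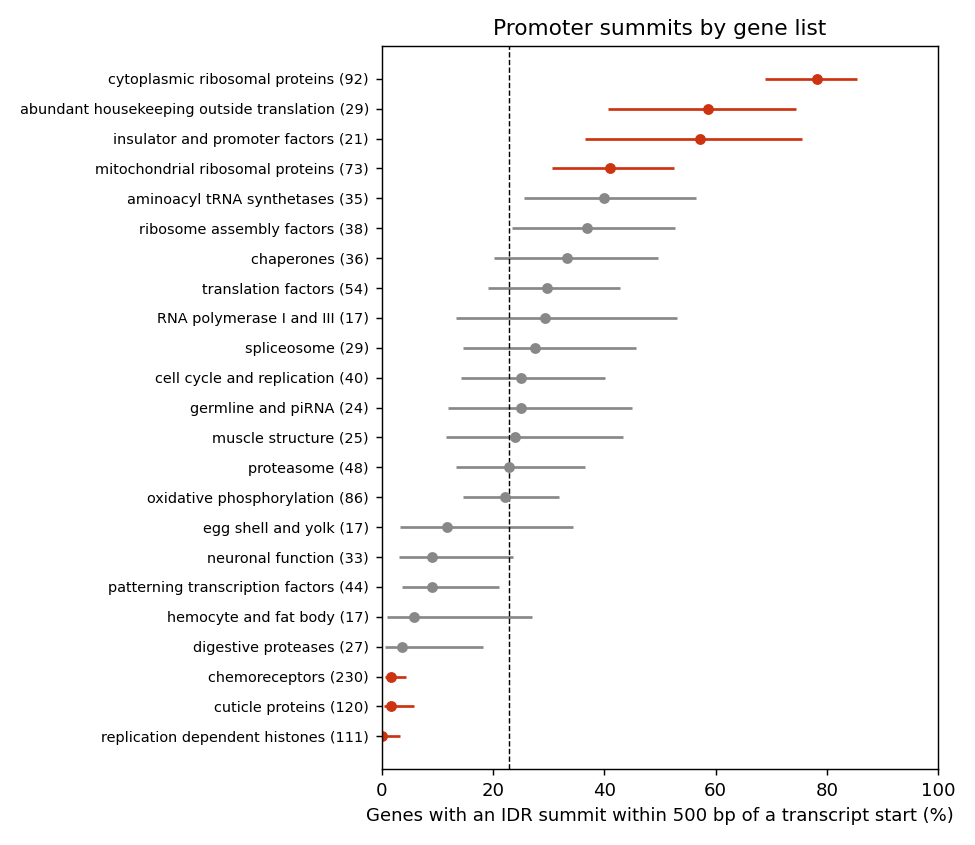
Share of genes with an IDR summit within 500 bp of a transcript start (%), by gene list, with 95% Wilson intervals and the number of genes in brackets. Red lists pass, the dashed line is the 22.8% of all protein-coding genes, and cytoplasmic ribosomal protein genes stand highest, at 78.3%.

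Among bound genes, peak strength did not separate the lists: 0 of 15 passed by the permutation test of mean signal percentile. At an unadjusted p under 0.05 were cytoplasmic ribosomal protein genes (66.9 ± 19.5, SD over 72 genes, against 59.9, permutation p = 0.0392) and insulator and promoter factor genes (76.0 against 59.99, permutation p = 0.0468), both with an adjusted p of 0.309.

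Among genes that make non-coding RNA, 212 of 1945 long non-coding RNA genes had a summit within 500 bp of their start (10.9%, 1.87 times chance, permutation adjusted p = 0.006). So had 42 of 290 tRNA genes (14.5%, 2.53-fold, permutation adjusted p = 0.006), led by tRNA:Tyr-GTA-1-8, tRNA:Leu-TAA-2-1 and tRNA:Gln-TTG-2-1, and 8 of 32 snRNA genes (25%, 4.36-fold, permutation adjusted p = 0.012), led by snRNA:U2:34ABb and snRNA:U1:95Ca, the latter matched in replicate 2 alone. The summit lay inside the gene for 1 of the 42 tRNA genes and 5 of the 8 snRNA genes. Among long non-coding RNA genes the strongest peaks were those of lncRNA:CR44463 (443 bp downstream of its start) and lncRNA:CR44120 (367 bp downstream). These are also the peaks upstream of mRpL41 and SLC5A11. The peaks of lncRNA:CR44339 and lncRNA:CR31044 lay 147 and 113 bp upstream. In all these classes a summit nearer a neighbouring gene's start was counted too, and nearest starts only were not tried. The tRNA share differed between replicates 1, 2 and 3, at 8.97%, 25.9% and 19.7%. The tRNA fold was 2.42 without replicate 1 (permutation adjusted p = 0.006). It was 1.45 without replicate 2 (permutation adjusted p = 0.396) and 1.43 without replicate 3 (permutation adjusted p = 0.432). The latter 2 settings require a match in replicate 1, where the tRNA share was lowest. In the upper 4094 peaks the tRNA fold was 1.29 (permutation adjusted p = 0.77) and the snRNA fold 4.21 (permutation adjusted p = 0.174). snoRNA genes (26 of 269, 1.74-fold, permutation adjusted p = 0.171), led by snoRNA:Psi28S-2949, and pre-miRNA genes (13 of 260, 0.848-fold, permutation adjusted p = 0.739), led by mir-9377 and mir-ban, did not pass. With a 1000-bp window snoRNA genes passed (72 of 269, 2.58-fold, permutation adjusted p = 0.00799). Of 99 rRNA genes on the arms 0 had a summit, which allows up to 3.03% were they independent (Wilson upper limit 3.74%). This did not differ from the 5.07% of shifts by the test (permutation adjusted p = 0.739), and these genes are clustered repeats in which reads may not be placed uniquely.

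By arm, X had the highest density of peaks, 69.9 per Mb (1.17 times its share of length, binomial adjusted p = 5.9e-12), and 67.6 ± 1.36 per Mb (SD, 3 replicates) in the replicates' own lists. Arms 2L (64.4 per Mb, 1.08-fold, binomial adjusted p = 0.00127) and 3L (63.7, 1.07-fold, binomial adjusted p = 0.0018) were above their share and 2R below it (53.9, 0.905-fold, binomial adjusted p = 6.5e-05). Arm 4 carried 15 peaks, 11.1 per Mb (0.187-fold, binomial adjusted p = 2.2e-18), and the replicates' own lists had more, 12.6, 17.1 and 24.5 per Mb. Arm 3R did not differ by the test (0.975-fold, binomial adjusted p = 0.219). Arm Y had 0 of the 8188, which allows up to 0.0366%, against 218 expected by length (binomial adjusted p = 1.2e-95) and 39.0 by transcript starts (binomial adjusted p = 5.1e-17). The pooled list and the replicates' full lists had no summit on Y either, so peaks there may not have been callable. The shares of length and of transcript starts include Y, so in that case the folds of all other arms stand too high. No comparison without Y was made, and calls by length with small folds, as for 2L, 3L and 3R, may depend on it. The embryos were of mixed sex, so copy number of X and Y differs from the other arms. These limits on the X and Y counts were not tested. Against the share of transcript starts, 2L was below instead of above its share (0.953-fold, binomial adjusted p = 0.045), and this did not pass in the upper 4094 peaks (0.961-fold) or without any 1 replicate. Arm 3L did not pass by length in the upper 4094 peaks (1.06-fold).

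The fourth question is what sequence the peaks contain. The DRE, the palindrome TATCGATA bound by DREF, was in 2.08% of summit windows against 0.507% of flanks (4.10-fold, exact adjusted p = 1.2e-18), and was 2.46 times as frequent as in GC-matched windows. Motif 1, bound by M1BP, was 3.44 times as frequent as in flanks (exact adjusted p = 4.7e-06) and the core promoter motif called Ohler 7 was 1.63 times as frequent (exact adjusted p = 5.5e-09). CGATA, the BEAF-32 core, was 1.11 times as frequent (exact adjusted p = 0.00017). TATA boxes (1.98-fold), GATA sites (1.28-fold) and Ohler 6 (2.82-fold) passed against flanks but not against GC-matched windows (1.08-fold, 1.02-fold and 1.26-fold). CCAAT boxes (0.929-fold) and Pho sites (0.793-fold) were fewer than in flanks. Myc E-boxes (0.534-fold), GAGA repeats (0.639-fold) and the CTCF core (0.815-fold) were also fewer than in flanks, but against GC-matched windows GAGA repeats (1.39-fold, exact adjusted p = 0.00661) and the CTCF core (1.502-fold, exact adjusted p = 2.3e-08) passed in the opposite direction. Myc E-boxes did not pass there (1.05-fold, exact adjusted p = 0.822). In the upper 4094 peaks Motif 1 (2.27-fold), Ohler 6 (1.79-fold) and CGATA (1.07-fold) did not pass, nor Ohler 6 without replicate 3 (1.93-fold), nor in narrower windows did CGATA (1.03-fold) and the CTCF core (0.853-fold). Motif 1 stood at 7.86-fold against GC-matched windows and 7.33-fold against flanks 500 bp away.

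Around gene starts, bound genes more often had Ohler 7 (11.4% against 6.19% of other genes, odds ratio 1.96, Fisher adjusted p = 6.5e-20), the DRE (10.7% against 6.99%, 1.59, Fisher adjusted p = 2.8e-10) and GAGA repeats (1.65, Fisher adjusted p = 1.9e-06). Ohler 6 (1.56), Ohler 5 (1.52), Motif 1 (1.44), Myc E-boxes (1.36), CGATA (1.26) and the TCT initiator (1.17) were also more frequent. TATA boxes were less frequent (6.495% against 12.0%, odds ratio 0.509, Fisher adjusted p = 2.1e-19), as were the Initiator (0.724), Pho (0.825) and GATA sites (0.883). Ohler 6 did not pass without replicate 2 (1.24) or 3 (1.31), nor did Myc E-boxes and Motif 1 in the upper 4094 peaks (1.34 and 1.26), Myc E-boxes without replicate 3 (1.29) or GATA with a 250-bp promoter (0.905). Pho did not pass under 4 of the 6 alternatives. The DPE pattern used was found in over 99% of windows and separates nothing.

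Summits lay in AT-rich DNA. Windows around IDR summits had a mean GC content of 33.5%, against 41.8% in windows 1000 bp away and 42.4% at shifted positions, and the replicates' own summits had 33.9% ± 0.451 (SD, n = 3). Promoters were bound more often where their lowest GC content was low: of 10 groups of genes ordered by it, 36.8% of the lowest were bound and 11.7% of the highest. The lowest value was taken over all annotated starts of a gene, and a summit near any start counted. Genes with more starts can thus have both a lower value and more chances to be bound, which was not separated here.

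**Figure D4:**
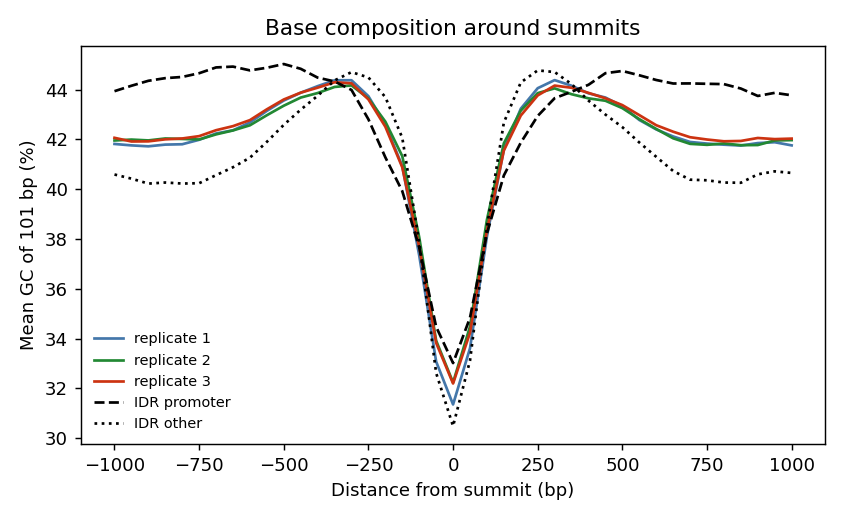
Mean GC content (%) in a sliding window by distance from the summit (bp), for the 8188 strongest peaks of each replicate and for IDR summits in promoters and elsewhere. At the summit the mean is 33.0% for IDR summits in promoters and 30.5% for those elsewhere. At 300 bp toward lower coordinates it is 44.0% and 44.7%.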

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

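The alternatives matched on GC and the shifts confined to the span with peaks were chosen after the data were seen; the others were planned. Of 87 alternative values of the main counts, shares, folds and correlations, 80 stayed as they were by the rule set for each. For folds the rule asked for the same direction and the same side of 0.05. For shares found in replicates it asked only for more than shifts at p under 0.05. Those shares themselves moved: replicate overlap ran from 64.1% to 84.9%. IDR peaks among the strongest of all 3 replicates ran from 54.5% to 95.4%. The count of 80 is thus no measure of unchanged size. The promoter fold ranged from 2.04 to 3.61 and the coding-exon fold from 0.007 to 0.0458. Fewer non-coding classes passed in the upper 4094 peaks, 1 against 3, and 4 passed with a 1000-bp window, where snoRNA genes gained the threshold (2.58-fold). The rank correlations moved by more than their spread: with summits within 50 bp they were 0.902, 0.913 and 0.912, and within 250 bp 0.855, 0.868 and 0.867; a tighter match keeps fewer peaks, and the cause was not tested further. The top 8188 pooled peaks were planned as an alternative but are the IDR list itself. Unknown read depth limits every list.

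Every estimate that crossed no difference is given here. Where a range over left-out replicates spans no difference, only its values on the side opposite to the main estimate crossed. Introns stood at 0.951 with a 1000-bp promoter and matched on GC at 0.945, and at 0.954 and 0.927 with the smaller and larger window. Of 226 list values 26 crossed, none of them past the threshold. In the upper 4094 peaks they were RNA polymerases 0.533, proteasome 0.741 and oxidative phosphorylation 1.08. Leaving out replicates gave proteasome 0.669 to 0.813, muscle 0.916 to 0.966, spliceosome 0.814 to 1.247, oxidative phosphorylation 0.847 to 1.10 and germline 0.961 to 1.58. With a 250-bp promoter muscle was 0.736, and with 1000 bp proteasome was 0.834 and oxidative phosphorylation 1.01. Among genes with a pooled-list peak muscle was 0.495 and cell cycle 0.908. With nearest starts only, ribosome assembly was 0.759, proteasome 0.971 and spliceosome 0.611. With gene 5′ ends only, oxidative phosphorylation was 1.14 and muscle 0.824. In GC strata proteasome was 0.994, muscle 0.957 and germline 0.930. Of 74 differences in signal percentile 14 crossed 0. Mean replicate ranks gave muscle -0.0105 and germline 0.704. The 250-bp promoter gave spliceosome 5.61, cell cycle 0.871 and housekeeping -6.37. Leaving out replicates gave mitochondrial ribosomal -0.725 to 0.570, muscle -0.666 to 1.55, germline 0.0814 to 1.32, cell cycle -1.43 to 0.413 and housekeeping -1.02 to 1.71. Pre-miRNA genes stood at 1.21 within 1000 bp. At summits the TCT initiator was 1.01 in the upper 4094 peaks and 1.00037 to 1.02 without a replicate; matched on GC, Myc was 1.05, GAGA 1.39, the CTCF core 1.502 and the DPE 1.00123. At gene starts, C/EBP was 0.578 and AP-1 1.11 in the upper 4094 peaks, and AP-1 was 1.02 to 1.03 without a replicate. Causes were not tested.

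Of the list values that kept their direction, 16 gained and 6 lost the threshold. Ribosome assembly factors, aminoacyl-tRNA synthetases, patterning factors, neuronal genes and digestive proteases passed under at least 1 alternative. Of 140 motif values at summits 15 gained and 9 lost it, and of 120 at gene starts 10 lost it.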

Other observations

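All tests in this part were chosen after the results they bear on had been seen. The design has 1 group, so no biological explanation was tested by a comparison of groups, and high transcription was weighed only through a gene list.

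Bound ribosomal protein genes had their summits nearer the transcript start than other bound genes. Their mean position was -33.5 ± 59.7 bp (SD over 72 genes), against -153 ± 169 bp for the other 3115 bound genes, a difference of 119 bp (two-sided permutation p = 2e-05, the smallest that 100000 resamples can give). Each gene took its strongest promoter summit, also where that summit lay nearer a neighbour's start, as for mRpS23 (382 bp upstream). Part of the difference may come from such shared summits, which were not separated here. Mitochondrial ribosomal protein genes had a median of -154 bp over 30 genes and ribosome assembly factors -164 bp over 14. The median of all bound genes was -150 bp, and 8 other lists lay nearer the start than that, from -139 bp for spliceosome genes to -79.5 bp for translation factors. The gene holding the most IDR summits was kirre (45 in 394 kb), followed by Ten-a (22 in 292 kb) and CG1677 (21 in 125 kb). Annotated transposons held 21 summits (0.256%, Wilson interval 0.168 to 0.392) and make up 5.71% of the DNA spanned by peaks. How reads in repeats were filtered is not given in the sources used here. Within 25 kb of Noc1 there were 8 IDR summits, against an arm median of 2, above 88.8% of windows on 3L, but the pooled list had 17 against 10 (above 69.2%) and replicates 1, 2 and 3 had 18 against 11, 19 against 10 and 28 against 11 (above 73.6%, 73.8% and 91.6%).

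The scarcity of summits in coding exons and their AT-rich sequence could come from a preference for AT-rich fragments in recovery or peak calling. Against positions of equal GC content the coding-exon fold was still 0.0458 and the promoter fold 2.62, which argues against composition as the whole cause, although matching raised the coding-exon fold from 0.0116. With histone genes and transposons left out the fold was 0.0425, so these do not make the scarcity. This cannot decide whether other repeated exons were lost, which was not examined. Transposons were not in the exon annotation and histone genes hold only 14.9 kb outside promoters, so leaving them out could hardly move the fold. A contribution of composition, of the control reads or of the antibody stays open, because neither the control nor an untagged line was analysed here.

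The frequent binding of ribosomal protein promoters may reflect their sequence composition, neighbouring genes or high transcription. Within strata of promoter GC the odds ratio was 11.8, and with each summit given to its nearest start it was 15.8, which argues against composition and neighbours as the whole cause. Abundant housekeeping genes without the shared member were bound in 17 of 28 cases (60.7%), 17.5 percentage points below ribosomal protein genes (two-sided Fisher exact p = 0.0841). In the replicates' own lists the shares were 62.1%, 69.0% and 72.4% for the whole housekeeping list and 76.1%, 81.5% and 79.3% for ribosomal protein genes. High transcription therefore cannot be told apart from a property of these promoters, as transcript levels were not measured here.

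An 8-base word, CACTGAGA, was found by counting all words at summits outside promoters and may mark a sequence preference, there and at promoters. At promoters it was in 1.84% of 3036 windows against 0.313% of flanks (exact p = 2.0e-09) and 0.560% of GC-matched windows. Outside promoters it was in 5.90% of 5152 windows against 0.738% of flanks and 0.563% of GC-matched windows (10.5 times the latter), and in 5.88%, 5.60% and 5.56% in replicates 1, 2 and 3. For pooled peaks outside the IDR list and outside promoters the share was 1.81%, against 0.771% of flanks. The word lay a median of 68 bp from IDR summits outside promoters, in windows reaching 100 bp to each side. It was thus mostly beside the summit and not centred on it. Among common words it had the largest ratio over flanks on arms 2L, 2R and 3L (6.39% of 2866 windows against 0.750%). On the other arms it was in 5.29% of 2286 windows against 0.722% of flanks. The same data had been looked at before, so this split is not a held-out test. Over all arms its exact sign-test p against flanks, multiplied by the 32896 possible words, was 9.2e-47, which argues against the largest of many chance ratios. The GC-matched share argues against GC content as the whole cause, and the commonest base 11 to 20 bp away, averaging 31.9% with 0% of words in transposons, argues against copies of a repeat. Which protein binds the word was not tested, and indirect recruitment, open chromatin or sequence composition beyond GC content stays open.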
